A study of Homo sapiens with 30 samples.

How the data were processed

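Strand-specific messenger RNA libraries (KAPA Stranded mRNA-Seq, per the labels' protocols) were made from LNCaP cells plated at 130000 per well in medium with 8% hormone-depleted serum, kept without androgen for 48 h and then treated for 24 h with vehicle or R1881 at 0.03, 0.06, 0.1 or 10 nM. Per the submitters' processing notes the reads were handled with Trimmomatic 0.39, STAR 2.7.8a and DESeq2 1.36.0 on GRCh38/hg38; the read counter, the annotation release and the strand setting are not given. The deposited table holds raw whole-number counts per Ensembl gene, 1 column for each of 15 libraries, and lists 37843 genes; no gene has 0 counts in every library. The series has 30 samples. The other 15 are VCaP cells, and the columns of their table match no label, so no library can be given a dose; every VCaP comparison, the comparison between lines and the overlap between lines were left out.

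Groups were taken from the labels, 3 libraries each (replicates 2, 3 and 4), and replicate numbers were read from the column names. Gene IDs were matched without version to a symbol table (37732 matched, 28455 with a symbol), and positions are those of GENCODE 29 on GRCh38. Of the 162 genes named by rule, 14 overlap another gene on the same strand and 53 on the opposite strand, and 1 (PCSEAT) had no position. CPM values are counts over effective library sizes, that is library totals times TMM factors, whose mean ran from 1.04 ± 0.0162 in vehicle to 0.902 ± 0.0166 at 10 nM (SD, n = 3). Total counts of 30666460 to 61199483 per library set the precision: 95% intervals for genes with 1 to 3 counts in a group are exact counting intervals, and a group with 0 counts was set to a floor of 3 counts over the group. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

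Gene tests used edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group (18403 genes tested), quasi-likelihood fits to all 15 libraries with 1 mean per group, two-sided tests and Benjamini-Hochberg adjusted p under 0.05. The comparisons were each dose against vehicle and 10 nM against 0.06 nM, the latter because 0.06 nM is the highest low dose of both lines in the design. A gene was non-monotone if the calls of 0.06 nM against vehicle and 10 nM against 0.06 nM had opposite signs. The 24 gene lists were tested with limma 3.58.1 camera (preset correlation 0.01) on log2 CPM with a prior count of 2, adjusted over 115 tests of the 23 lists with enough members in 5 comparisons; camera with an estimated correlation and fry, which asks only whether a list's own genes move one way, were run beside it. The lists were those for androgen-induced and androgen-repressed genes, DNA replication, mitosis, cell cycle inhibitors, ribosome biogenesis, cholesterol and fatty acid synthesis, the unfolded protein response, ATF4 targets, glycolysis, hexosamine and polyamine synthesis, DNA repair, p53 targets, glucocorticoid-responsive genes, interferon response, the insulin-like growth factor axis, ETS factors, mitochondrially encoded genes, and prostate luminal, prostate basal, neuroendocrine, fibroblast, and leukocyte and endothelial markers. Groups, comparisons, tests, gene lists, the rule for named genes and the alternatives not stated as added later were fixed before the data were examined; the adjustment over 115 tests replaced 1 over both lines. Fisher's exact test compared the lists with the non-monotone genes among all tested genes (48 tests).

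Named genes were the 8 largest rises and falls for 0.06 nM, 10 nM and 10 nM against 0.06 nM, and the 3 largest for the other doses. These had a symbol, a mean of at least 5 CPM in at least 1 group, a call and no overlap between the groups' libraries. To these came 6 peaks and 6 troughs with a symbol and the same CPM floor, without the condition on overlap. Genes fixed in advance (KLK3, FKBP5, TMPRSS2, ERG, ETV1, MYC, CDKN1A and NR3C1 among them) were named without these conditions. So were up to 4 members of each called list, those with the smallest p, whether or not they were called. Some genes that this rule names are not reported here. Other list members are named only to complete a count of few members, or as stated. Alternatives were RLE size factors, DESeq2 1.42.0, no low-count filter, a stricter filter (at least 1 CPM in 3 libraries and a mean count of 20), the replicate number as a block, only the libraries compared, and leaving out each library in turn. Library totals without TMM factors, thinning of all libraries to the smallest total and leaving out the 5 libraries numbered 3 were added after the data were seen. The tests were checked on simulated data with 200 changed genes at the libraries' own dispersions. Of genes changed by a log2 of 0.5, 1 and 2, the 0.06 nM comparison recovered 50.7%, 79.1% and 93.9% (3 false calls of 152). The 10 nM comparison recovered 52.2%, 76.1% and 92.4% (7 of 154). In the data far more genes were called in these comparisons (31.2% and 57.6% of those tested), so these rates need not hold there.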

Results

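Messenger RNA was sequenced from LNCaP cells, an androgen-sensitive line derived from a lymph node metastasis of prostate cancer, after 24 h with vehicle or with 0.03, 0.06, 0.1 or 10 nM of R1881, a synthetic androgen that is not aromatised. Each of the 5 groups held 3 libraries, numbered 2, 3 and 4, and the labels do not say whether these came from separate cultures. The series asks how low and high androgen doses differ, in connection with a response of prostate cancer cells that is biphasic, rising and then falling with dose. Total counts per library ran from 30666460 (0.06 nM replicate 3) to 61199483 (10 nM replicate 3), from 40396721 to 43963087 in vehicle, 35102621 to 47166747 at 0.03 nM, 30666460 to 39532215 at 0.06 nM, 33422397 to 46618984 at 0.1 nM and 41596157 to 61199483 at 10 nM. The 5 libraries numbered 3 stood apart from the others on the third principal component (5.86% of variance), and mitochondrially encoded genes took 9.31% to 10.7% of their counts against 6.14% to 7.69% in the other 10 libraries; each group held 1 of them. Levels are depth-scaled counts (CPM) as mean ± SD, fold changes are on the log2 scale ± SE, and n = 3 libraries per group throughout.

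**Figure D1:**
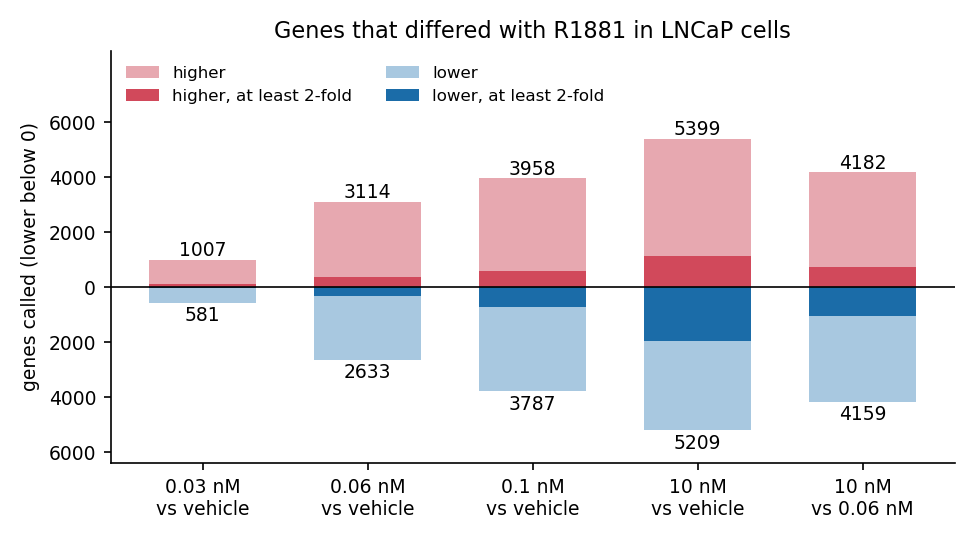
Genes called higher (upward bars) and lower (downward bars) in each comparison of LNCaP groups of 3 libraries, on an axis of number of genes, with the darker part of each bar showing changes of at least 2-fold. Calls against vehicle grew from 1588 genes at 0.03 nM to 10608 at 10 nM.

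At 0.03 nM, the lowest dose, classical androgen targets were already far above vehicle. KLK3, which encodes prostate-specific antigen (ENSG00000142515.15, chromosome 19, 50854915 to 50860764, plus strand, GRCh38), went from 103 ± 7.65 to 775 ± 106 CPM, a rise of 7.55-fold (log2 2.92 ± 0.09, edgeR adjusted p = 5.08e-13). The largest rises were in TRPM8, a cold-sensing cation channel (log2 3.76 ± 0.24), KLK2, a kallikrein protease and close paralog of KLK3 (3.57 ± 0.096), and CHRNA2, a nicotinic acetylcholine receptor subunit (3.30 ± 0.16). TMPRSS2, a membrane serine protease, rose 2.85-fold and FKBP5, a co-chaperone of steroid receptors, 1.64-fold. The largest falls were in PLD1, a phospholipase D (log2 -1.39 ± 0.16), AOC1, diamine oxidase (-1.35 ± 0.18), and MAN1A1, a mannosidase of N-glycan trimming (-1.34 ± 0.16).

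Of the 28 measured androgen-induced genes 23 rose and none fell at 0.03 nM, 26 when adjusted over the list alone. Androgen-induced genes had adjusted p = 2.66e-36 by camera and adjusted p = 0.0332 with an estimated correlation. DNA replication genes rose almost as a block, 35 of 38 with a median log2 change of 0.56 and 37 when adjusted over the list alone. DNA replication genes had adjusted p = 2.27e-31 by camera and adjusted p = 0.0844 with an estimated correlation. Among them, CDC6, a loader of the replicative helicase, rose by 0.86 ± 0.099 and DTL by 0.95 ± 0.11. DNA repair genes rose in 15 of 23 cases, 18 when adjusted over the list alone, with RAD54L, a motor protein of homologous recombination, at 0.68 ± 0.098. DNA repair genes had adjusted p = 5.35e-12 by camera and adjusted p = 0.109 with an estimated correlation. Ribosome biogenesis genes rose in 12 of 28, 13 when adjusted over the list alone. Ribosome biogenesis genes had adjusted p = 1.09e-09 by camera and adjusted p = 0.122 with an estimated correlation. The same test called higher the prostate luminal markers, hexosamine and polyamine synthesis, cholesterol synthesis and glycolysis. Prostate luminal markers had adjusted p = 0.000297 by camera and adjusted p = 0.0584 with an estimated correlation. Hexosamine and polyamine synthesis had adjusted p = 0.000452 by camera and adjusted p = 0.0648 with an estimated correlation. Cholesterol synthesis had adjusted p = 0.000428 by camera and adjusted p = 0.191 with an estimated correlation. Glycolysis had adjusted p = 0.00432 by camera and adjusted p = 0.241 with an estimated correlation. Of their members 8 of 17, 9 of 12, 19 of 24 and 15 of 20, in that order, did not pass the test of single genes, and among those that did, ACP3, HOXB13 and STARD4 fell. Adjusted over the list alone, 8 luminal genes rose and ACP3, HOXB13 and FOXA1 fell, 11 cholesterol genes rose and STARD4 fell, 6 glycolysis genes rose, and UAP1, GNPNAT1, SAT1, SRM and NANS rose in the hexosamine and polyamine list. The call on glycolysis was lost when the 5 libraries numbered 3 were left out. Examples of members that rose were SORD, sorbitol dehydrogenase (log2 0.44 ± 0.072), UAP1, an enzyme of UDP-GlcNAc synthesis (0.63 ± 0.061), and HK2, a hexokinase (0.39 ± 0.08).

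Over all genes edgeR called 1588 of 18403 tested at 0.03 nM, 1007 higher and 581 lower, with 117 and 35 changed at least 2-fold. The 1588 became 979 without vehicle replicate 4 and 1008 when only the libraries compared were fitted. A further 4 lists were called at this dose (adjusted p of 0.000349 to 0.0322 by camera, and 0.128 to 0.587 with an estimated correlation). Each lost its camera call when certain single libraries were left out. For androgen-repressed genes and for p53 targets these were vehicle replicate 2 or 0.03 nM replicate 3. For mitosis it was vehicle replicate 3. For fatty acid synthesis they were vehicle replicate 4, 0.03 nM replicate 2 or 0.03 nM replicate 3. The calls on p53 targets and fatty acid synthesis were also lost without the 5 libraries numbered 3, and fry did not call mitosis. With the replicate number as a block, camera kept all 4 calls (adjusted p from 7.95e-12 for mitosis to 0.0467 for fatty acid synthesis).

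At 0.06 nM the same targets stood further above vehicle. KLK3 reached 1500 ± 96.1 CPM (log2 3.87 ± 0.093, adjusted p = 7.96e-15), FKBP5 rose from 58.1 ± 2.37 to 211 ± 8.37 CPM (1.86 ± 0.069) and TMPRSS2 from 66.4 ± 13.4 to 319 ± 87.2 CPM (2.26 ± 0.21). The largest rises were in CCDC141, a coiled-coil protein (0.114 ± 0.0457 to 6.99 ± 0.595 CPM, log2 5.90 ± 0.33), CHRNA2 (4.86 ± 0.15), KLK2 (4.81 ± 0.099) and TRPM8 (4.67 ± 0.23). PSLNR, a long noncoding RNA, rose by 4.15 ± 0.20, ST6GALNAC1, a sialyltransferase, by 3.97 ± 0.16, and F5, coagulation factor V, by 3.88 ± 0.22. The largest falls were in PLD1 (7.08 ± 1.09 to 0.933 ± 0.185 CPM, log2 -2.90 ± 0.18), MAN1A1 (-2.25 ± 0.17), AOC1 (-2.17 ± 0.19) and DAB1, an adaptor of reelin signalling (-1.93 ± 0.21). VWA2, a von Willebrand factor A domain protein (-1.92 ± 0.15), MYLK, myosin light chain kinase (-1.91 ± 0.08), LRRC31 (-1.89 ± 0.28) and DIPK2B (-1.78 ± 0.17) completed the 8 largest. MYC, a growth-promoting transcription factor, rose from 152 ± 1.27 to 206 ± 7.89 CPM (0.44 ± 0.058), and CDKN1A, the cell cycle inhibitor p21, fell from 148 ± 13 to 111 ± 6.83 CPM (-0.41 ± 0.084).

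Of the 28 androgen-induced genes 27 rose at 0.06 nM, 27 when adjusted over the list alone, with a median log2 change of 1.54; TIPARP was the exception. Androgen-induced genes gave adjusted p = 1.61e-30 by camera and adjusted p = 0.0332 with an estimated correlation. Every one of the 38 DNA replication genes rose, 38 also when adjusted over the list alone, with a median of 0.95. DNA replication genes gave adjusted p = 1.25e-27 by camera and adjusted p = 0.107 with an estimated correlation. Of these, the helicase subunit MCM5 rose from 54.9 ± 3.75 to 122 ± 3.32 CPM, FEN1, the flap endonuclease, by 1.17 ± 0.10, and DTL by 1.40 ± 0.11. Mitosis genes rose in 22 of 32 cases, 29 when adjusted over the list alone, CDK1 by 0.80 ± 0.15 and ANLN, a cytokinesis scaffold, by 0.93 ± 0.13. Mitosis genes gave adjusted p = 1.09e-07 by camera and adjusted p = 0.394 with an estimated correlation. When the replicate number was added as a block, camera with an estimated correlation gave adjusted p = 0.0931 for mitosis and for DNA replication alike, without a call. DNA repair genes rose in 20 of 23, 20 with 1 lower when adjusted over the list alone, and FANCA, of the Fanconi anaemia pathway, rose by 0.98 ± 0.092. DNA repair genes gave adjusted p = 1.97e-11 by camera and adjusted p = 0.117 with an estimated correlation. Ribosome biogenesis genes rose in 23 of 28, 27 when adjusted over the list alone, among them NOP16 (0.65 ± 0.076) and LYAR (0.80 ± 0.093). Ribosome biogenesis genes gave adjusted p = 1.98e-12 by camera and adjusted p = 0.0844 with an estimated correlation.

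The lists for lipid and sugar genes were also called higher at 0.06 nM by camera with its preset correlation. Cholesterol synthesis had 17 of 24 members higher and 3 lower (HSD17B7, STARD4 and TM7SF2), 19 and 3 when adjusted over the list alone. Cholesterol synthesis gave adjusted p = 8.93e-08 by camera and adjusted p = 0.0763 with an estimated correlation. INSIG1, a sterol-sensing regulator of that pathway, rose by 0.61 ± 0.068 and IDI1, an isomerase of it, by 0.49 ± 0.062. Fatty acid synthesis had 11 of 20 higher and ACSL4 lower, 11 and 2 when adjusted over the list alone; the elongase ELOVL7 rose by 2.24 ± 0.12. Fatty acid synthesis gave adjusted p = 0.000133 by camera and adjusted p = 0.161 with an estimated correlation. In hexosamine and polyamine synthesis 9 of 12 members were higher, 9 when adjusted over the list alone. Hexosamine and polyamine synthesis gave adjusted p = 5.15e-05 by camera and adjusted p = 0.0557 with an estimated correlation. Glycolysis had 11 of 20 higher and PFKM lower, 12 and 1 when adjusted over the list alone. Glycolysis gave adjusted p = 5.65e-05 by camera and adjusted p = 0.117 with an estimated correlation. The unfolded protein response, the programme of the endoplasmic reticulum for misfolded protein, had 11 of 22 higher, 12 with 1 lower when adjusted over the list alone. The unfolded protein response gave adjusted p = 0.000504 by camera and adjusted p = 0.126 with an estimated correlation. Prostate luminal markers had 10 of 17 higher and 4 lower (ACP3, CD24, FOXA1 and HOXB13), the same numbers when adjusted over the list alone. Prostate luminal markers gave adjusted p = 0.00145 by camera and adjusted p = 0.0801 with an estimated correlation. Androgen-repressed genes had 7 of 14 lower and HSD17B6 higher, 8 and 1 when adjusted over the list alone, with CAMK2N1, an inhibitor of CaM kinase II, at -1.10 ± 0.13. Androgen-repressed genes gave adjusted p = 0.00498 by camera and adjusted p = 0.107 with an estimated correlation. p53 targets had 7 of 20 lower and AEN higher, the same numbers when adjusted over the list alone, a list call lost without vehicle replicate 2 or without 0.06 nM replicate 4. The p53 targets gave adjusted p = 0.0267 by camera and adjusted p = 0.151 with an estimated correlation.

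edgeR called 5747 genes at 0.06 nM, 3114 higher and 2633 lower, of which 358 and 337 changed at least 2-fold. Library totals alone, an alternative added after the data were seen, gave 2542 higher and 2896 lower. The reads of TTN and CCDC141, which overlap on the same strand of chromosome 2 (178525989 to 178830802 and 178829757 to 179050086), and of the paralogs KLK2 and KLK3 were divided in a way the labels do not give, so the split within each pair is not known.

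At 0.1 nM KLK3 stood at 2090 ± 77.4 CPM (log2 4.35 ± 0.095 against vehicle, adjusted p = 1.6e-15) and FKBP5 at 481 ± 43 CPM (3.05 ± 0.071). The largest rises were in SLC38A4, an amino acid transporter (0.0303 ± 0.0122 to 8.84 ± 1.14 CPM, 8.04 ± 0.30), TTN, titin (7.66 ± 0.46), and CCDC141 (7.04 ± 0.29). PLD1 (-3.68 ± 0.20), DAB1 (-3.14 ± 0.24) and MAN1A1 (-2.88 ± 0.18) fell most. MYC was still above vehicle (0.38 ± 0.058). All 28 androgen-induced genes rose (median 2.14), as did all 38 DNA replication genes (median 1.10), both also when adjusted over the list alone. Androgen-induced genes had adjusted p = 1.01e-28 by camera and adjusted p = 0.0332 with an estimated correlation. DNA replication genes had adjusted p = 9.28e-24 by camera and adjusted p = 0.122 with an estimated correlation. Mitosis genes rose in 29 of 32, 31 when adjusted over the list alone. Mitosis genes had adjusted p = 1.7e-08 by camera and adjusted p = 0.359 with an estimated correlation. In the unfolded protein response 17 of 22 members were now higher, 17 with 1 lower when adjusted over the list alone, with DNAJB9, a co-chaperone of the endoplasmic reticulum, at 0.84 ± 0.078. The unfolded protein response had adjusted p = 3.74e-06 by camera and adjusted p = 0.0648 with an estimated correlation. Of 12 genes of hexosamine and polyamine synthesis 10 were higher, also when adjusted over the list alone. Hexosamine and polyamine synthesis had adjusted p = 3.36e-06 by camera and adjusted p = 0.0393 with an estimated correlation. Among 20 p53 targets 11 were lower with TNFRSF10B and AEN higher, 12 lower when adjusted over the list alone. The p53 targets had adjusted p = 0.0155 by camera and adjusted p = 0.126 with an estimated correlation. Glucocorticoid-responsive genes had 7 of 13 higher and NR3C1, DUSP1, KLF9 and TSC22D3 lower, 5 lower when adjusted over the list alone. This list call was lost when the 5 libraries numbered 3 were left out, and with the replicate number as a block (camera adjusted p = 0.0917). Glucocorticoid-responsive genes had adjusted p = 0.0301 by camera and adjusted p = 0.201 with an estimated correlation.

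Over all genes edgeR called 7745 at 0.1 nM, 3958 higher and 3787 lower, and 603 and 711 changed at least 2-fold; library totals alone gave 3145 higher and 4486 lower. The other lists called at 0.06 nM kept their directions and calls at 0.1 nM, with adjusted p of 8.2e-11 to 0.00161 by camera and 0.0648 to 0.151 with an estimated correlation.

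At 10 nM, the high dose, several genes that were almost silent in vehicle became abundant. STEAP4, a metalloreductase (ENSG00000127954.13, chromosome 7, 88270892 to 88306891, minus strand), had no count in the 3 vehicle libraries and 142 ± 6.3 CPM at 10 nM, which is at least 6170-fold higher against a floor of 3 counts over the vehicle group. SLC2A3, the glucose transporter GLUT3, had 2 counts in vehicle and 2411 at 10 nM (1200-fold, 95% counting interval 332 to 9920), and ORM2, orosomucoid, an acute-phase plasma protein, 3 and 1214 (403-fold, 138 to 1960). TTN (10.00 ± 0.40), SLC38A4 (9.74 ± 0.27), CCDC141 (9.08 ± 0.27), TUBA3D, an alpha tubulin (8.71 ± 0.30), and PCSEAT, a long noncoding RNA (8.30 ± 0.34), were the other largest rises on the log2 scale. The established targets reached their highest levels: KLK3 3850 ± 79.6 CPM (5.23 ± 0.099, adjusted p = 4.31e-17), FKBP5 2450 ± 84.6 CPM (42.2-fold, 5.40 ± 0.079) and TMPRSS2 1340 ± 144 CPM (20.1-fold, 4.33 ± 0.23). The largest falls were in DAB1 (-5.55 ± 0.31), ABCA1, a cholesterol exporter (7.91 ± 2.43 to 0.167 ± 0.0993 CPM, -5.48 ± 0.48), OPRK1, the kappa opioid receptor (99.3 ± 8.65 to 2.25 ± 0.731 CPM, -5.43 ± 0.15), and AMIGO2, an adhesion molecule (-5.42 ± 0.18). PLD1 (-5.20 ± 0.23), VWA2 (-5.02 ± 0.20), DIPK2B (-4.73 ± 0.23) and MAN1A1 (-4.68 ± 0.21) followed.

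MYC went below vehicle at 10 nM, to 110 ± 2.55 CPM (-0.47 ± 0.058). ETV1, an ETS factor that is rearranged in LNCaP cells, rose from 178 ± 20 to 292 ± 5.42 CPM (0.71 ± 0.076). CDKN1A stood at 128 ± 7.81 CPM, a fall (-0.21 ± 0.083) whose call was lost without vehicle replicate 2 (adjusted p = 0.193), without 10 nM replicate 3 (0.0812) or without 10 nM replicate 4 (0.118). This call was also lost with RLE size factors (edgeR adjusted p = 0.0557), with DESeq2 (0.0767) and without the 5 libraries numbered 3 (edgeR, 0.0581). NR3C1, the glucocorticoid receptor, was under 1 CPM in every group and fell from 0.775 ± 0.236 to 0.144 ± 0.0805 CPM (-2.34 ± 0.47). ERG had 1 to 6 counts in each library and was not tested. Over all genes edgeR called 10608 of 18403 at 10 nM, 5399 higher and 5209 lower, of which 1131 and 1942 changed at least 2-fold.

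All 28 androgen-induced genes rose at 10 nM, with a median log2 change of 3.66 that was the same with STEAP4 at its bound. Androgen-induced genes reached adjusted p = 1.13e-23 by camera and adjusted p = 0.0393 with an estimated correlation. NDRG1, a stress-responsive protein, rose 41.5-fold and ACSL3, a long-chain acyl-CoA synthetase, 11.4-fold. Androgen-repressed genes fell in 10 of 14 and rose in 2, UGT2B11 and UGT2B28, chosen after their values were seen; ACKR3, a decoy chemokine receptor, fell by 3.01 ± 0.053 and BCHE, butyrylcholinesterase, by 2.65 ± 0.15. Androgen-repressed genes reached adjusted p = 0.000395 by camera and adjusted p = 0.0584 with an estimated correlation. Members of the unfolded protein response rose in 21 of 22 cases, with only ATF6 outside: SEC24D, a COPII coat protein, by 2.11 ± 0.076, DNAJB9 by 2.40 ± 0.078 and CREB3L4, a membrane-bound transcription factor, by 1.83 ± 0.079. The unfolded protein response reached adjusted p = 9.79e-12 by camera and adjusted p = 0.0332 with an estimated correlation. Of 12 genes of hexosamine and polyamine synthesis 10 rose, with ODC1, ornithine decarboxylase, going from 357 ± 25.5 to 2320 ± 355 CPM and SMS, spermine synthase, rising by 2.78 ± 0.09. Hexosamine and polyamine synthesis reached adjusted p = 5.43e-07 by camera and adjusted p = 0.0332 with an estimated correlation. Cholesterol synthesis rose in 22 of 24 and fell in 2, HSD17B7 and TM7SF2, and HMGCS1, which makes HMG-CoA, rose by 1.64 ± 0.047. Cholesterol synthesis reached adjusted p = 1.16e-09 by camera and adjusted p = 0.0584 with an estimated correlation. Fatty acid synthesis rose in 14 of 20 while MECR, ELOVL6 and ACSL4 fell; FASN, fatty acid synthase, went from 1870 ± 110 to 5370 ± 221 CPM. Fatty acid synthesis reached adjusted p = 5.75e-05 by camera and adjusted p = 0.141 with an estimated correlation. Glycolysis rose in 12 of 20 while PFKM fell, with the hexokinases HK2 and HK1 at 1.38 ± 0.079 and 1.12 ± 0.06. Glycolysis reached adjusted p = 0.00895 by camera and adjusted p = 0.276 with an estimated correlation.

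Prostate luminal markers rose in 11 of 17 while EPCAM, ACP3, CD24 and HOXB13 fell. The keratins KRT8 and KRT18, which overlap on opposite strands, rose by 2.62 ± 0.063 and 2.28 ± 0.06. Prostate luminal markers reached adjusted p = 8.19e-05 by camera and adjusted p = 0.0584 with an estimated correlation. Glucocorticoid-responsive genes rose in 7 of 13 while NR3C1 and MT2A fell, with ERRFI1, an inhibitor of the EGF receptor, at 4.21 ± 0.093 and SGK1, a kinase, at 3.69 ± 0.20. Glucocorticoid-responsive genes reached adjusted p = 0.00226 by camera and adjusted p = 0.103 with an estimated correlation. p53 targets fell in 17 of 20 while TNFRSF10B and AEN rose; TP53INP1 stood at -2.04 ± 0.095 and BBC3, the apoptosis inducer PUMA, at -1.58 ± 0.10. The p53 targets reached adjusted p = 5.68e-05 by camera and adjusted p = 0.051 with an estimated correlation. Interferon response genes fell in 13 of 21 while HERC6 and IRF7 rose, with CMPK2 at -1.23 ± 0.17 and MX1, an antiviral GTPase, at -0.83 ± 0.13. Interferon response genes reached adjusted p = 0.0216 by camera and adjusted p = 0.0763 with an estimated correlation. The 6 measured fibroblast markers all fell, FN1, fibronectin, from 366 ± 46.3 to 134 ± 16.4 CPM and COL1A1, a chain of type I collagen, from 32.6 ± 5.98 to 18.1 ± 1.85 CPM. Fibroblast markers reached adjusted p = 0.00457 by camera and adjusted p = 0.0584 with an estimated correlation. VWF and EMCN, the 2 measured leukocyte and endothelial markers, were also lower; with 2 members this list had no test. At 10 nM camera called neither ATF4 targets (3 of 23 higher, 7 lower) nor the insulin-like growth factor axis (6 and 3 of 9). It also did not call ETS factors (8 and 3 of 13) or cell cycle inhibitors (6 and 6 of 14). Prostate basal markers (KRT14 and LAMA3 higher, DST and ITGB4 lower, of 6) were not called by it. Neuroendocrine markers (SYP higher, POU3F2, ENO2 and NTS lower, of 5) and the 13 mitochondrially encoded genes (adjusted p = 0.492 by camera) were not called either. Of the last, edgeR called 0, with 1 (MT-CYB) at an unadjusted p under 0.05. DESeq2 called 2 of them, and edgeR 6 without the 5 libraries numbered 3. Fry in place of camera called the insulin-like growth factor axis, ETS factors and cell cycle inhibitors higher. It called prostate basal and neuroendocrine markers lower.

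Lists tied to cell growth and division were above vehicle at 10 nM in fewer members than at 0.1 nM: DNA replication in 27 of 38, mitosis in 22 of 32, 23 when adjusted over the list alone, DNA repair in 15 of 23 with ATM lower, and ribosome biogenesis in 18 of 28 with WDR12, POLR3G and MYC lower. DNA replication genes reached adjusted p = 7.48e-05 by camera and adjusted p = 0.532 with an estimated correlation. Mitosis genes reached adjusted p = 0.00277 by camera and adjusted p = 0.667 with an estimated correlation. DNA repair genes reached adjusted p = 0.00432 by camera and adjusted p = 0.475 with an estimated correlation. Ribosome biogenesis genes reached adjusted p = 0.00432 by camera and adjusted p = 0.446 with an estimated correlation. The counts of members in these 4 lists depended on the scaling of the libraries, although only ribosome biogenesis lost its list call. With library totals alone the median change of all genes at 10 nM moved by -0.21 and calls were 3069 higher and 7987 lower; 14 DNA replication genes were then higher and 2 lower, 6 mitosis genes higher, 7 DNA repair genes higher and 4 lower, and 9 ribosome biogenesis genes higher and 8 lower with no list call. The same scaling called the insulin-like growth factor axis higher at 10 nM. All other counts of list members at 10 nM were the same when adjusted over the list alone, and with library totals alone the unfolded protein response had 20 members higher, cholesterol synthesis 20 higher and 2 lower, hexosamine and polyamine synthesis 10 higher and 2 lower, fatty acid synthesis 12 higher and 3 lower, luminal markers 11 higher and 5 lower, p53 targets 18 lower and 1 higher, interferon response genes 15 lower and 1 higher, and glycolysis 7 higher and 7 lower.

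**Figure D2:**
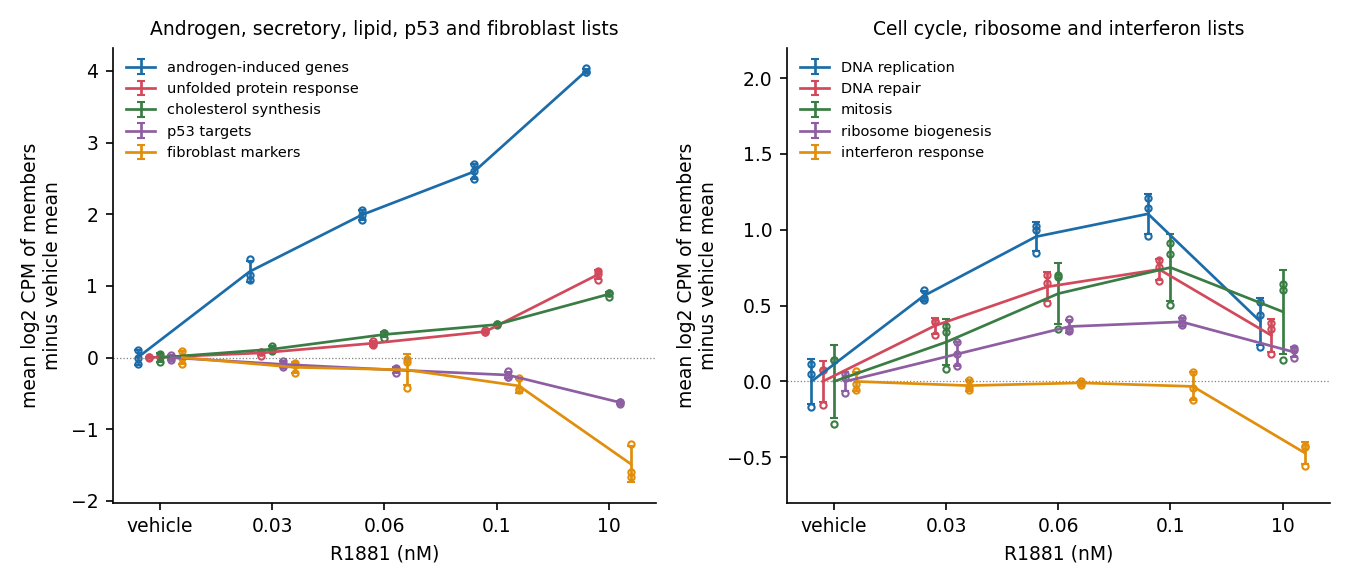
Mean log2 level of the members of 10 gene lists relative to the vehicle mean, by R1881 dose (doses evenly spaced, not to scale); points are the 15 libraries, lines join group means and bars are SD (n = 3). Androgen-induced genes, cholesterol synthesis and the unfolded protein response rose up to 10 nM, while DNA replication, DNA repair and ribosome biogenesis were highest at 0.1 nM.

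**Figure D3:**
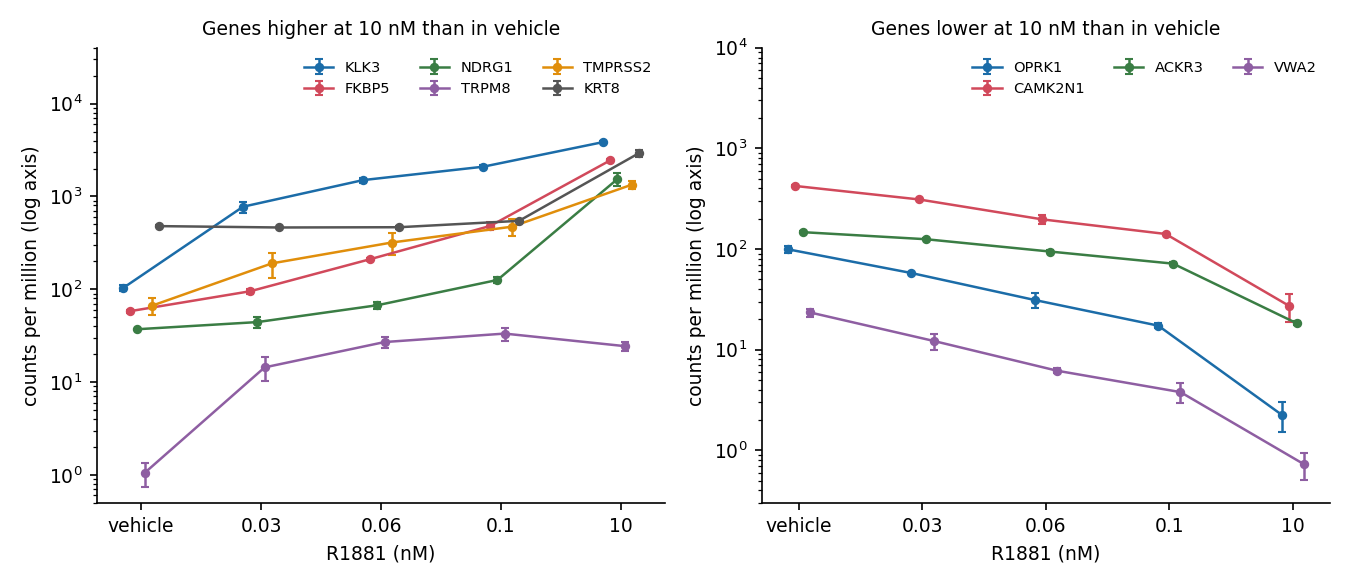
CPM on a log axis (mean ± SD, n = 3) by R1881 dose for 6 genes that were higher at 10 nM than in vehicle (KLK3, FKBP5, NDRG1, TRPM8, TMPRSS2, KRT8) and 4 that were lower (OPRK1, CAMK2N1, ACKR3, VWA2). KLK3 went from 103 to 3850 CPM and OPRK1 from 99.3 to 2.25 CPM.

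The direct comparison of 10 nM with 0.06 nM asks which genes separate the high from the low dose. NDRG1 went from 67.3 ± 5.98 CPM at 0.06 nM to 1540 ± 240 CPM at 10 nM (22.8-fold, log2 4.51 ± 0.12, adjusted p = 5.14e-15). STEAP4 (0.658 ± 0.121 to 142 ± 6.3 CPM, 7.74 ± 0.17), ORM1, the paralog of ORM2 (5.91 ± 0.28), NBL1, a secreted BMP antagonist that overlaps MINOS1 on the same strand (5.51 ± 0.24), SLC2A3 (4.81 ± 0.18), ORM2 (4.78 ± 0.20), EMP1, a membrane protein (4.73 ± 0.21), and PDE3A, a phosphodiesterase (4.60 ± 0.33), were higher by more. OPRK1 (-3.75 ± 0.16), IL1RN, the interleukin-1 receptor antagonist (-3.32 ± 0.15), VWA2 (-3.10 ± 0.21) and SI, sucrase-isomaltase (-2.94 ± 0.17), fell most among genes above the CPM floor. LRRN1 (-2.86 ± 0.16), CAMK2N1 (-2.85 ± 0.14), BRDT, a testis bromodomain protein (-2.58 ± 0.23), and PITX1-AS1, an antisense RNA that overlaps H2AFY on the opposite strand (-2.56 ± 0.15), came next. KLK3 was 2.56-fold higher, FKBP5 was higher by a log2 of 3.54 ± 0.072 and TMPRSS2 by 2.06 ± 0.21, while MYC (-0.91 ± 0.058) was lower.

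Androgen-induced genes were higher at 10 nM than at 0.06 nM in 27 of 28, all but TRPM8, with a median of 1.74. Androgen-induced genes gave adjusted p = 2.77e-20 by camera and adjusted p = 0.0533 with an estimated correlation. All 22 unfolded protein response genes were higher, DNAJB9 by 1.97 ± 0.077 and DNAJC3, a co-chaperone, by 1.27 ± 0.056. The unfolded protein response gave adjusted p = 2.74e-14 by camera and adjusted p = 0.0332 with an estimated correlation. So were 10 of 12 genes of hexosamine and polyamine synthesis, 20 of 24 of cholesterol synthesis with TM7SF2 lower and 12 of 17 prostate luminal markers with EPCAM lower. Hexosamine and polyamine synthesis gave adjusted p = 2.1e-07 by camera and adjusted p = 0.0332 with an estimated correlation. Cholesterol synthesis gave adjusted p = 2.11e-09 by camera and adjusted p = 0.0584 with an estimated correlation. Prostate luminal markers gave adjusted p = 3.02e-06 by camera and adjusted p = 0.0393 with an estimated correlation. Fatty acid synthesis was higher in 15 of 20, 16 when adjusted over the list alone, with MECR, ELOVL6 and ACSL4 lower, SCAP, the escort of SREBP, by 1.33 ± 0.055. Fatty acid synthesis gave adjusted p = 2.25e-05 by camera and adjusted p = 0.126 with an estimated correlation. Glucocorticoid-responsive genes were higher in 10 of 13 with MT2A lower, SGK1 by 3.56 ± 0.20. Glucocorticoid-responsive genes gave adjusted p = 5.65e-05 by camera and adjusted p = 0.0584 with an estimated correlation. Androgen-repressed genes were lower in 11 of 14 with UGT2B11 and UGT2B28 higher. Androgen-repressed genes gave adjusted p = 0.000185 by camera and adjusted p = 0.0584 with an estimated correlation. Of 20 p53 targets 14 were lower and TNFRSF10B higher, 14 and 2 when adjusted over the list alone. The p53 targets gave adjusted p = 0.000105 by camera and adjusted p = 0.0551 with an estimated correlation. Interferon response genes were lower in 12 of 21, 13 when adjusted over the list alone, with HERC6 and IRF7 higher. Interferon response genes gave adjusted p = 0.00837 by camera and adjusted p = 0.0584 with an estimated correlation. All 6 fibroblast markers were lower, with LUM losing its call without 0.06 nM replicate 2 (adjusted p = 0.0659), 0.06 nM replicate 4 (0.0523) or 10 nM replicate 2 (0.0517). LUM also lost its call when all libraries were thinned to the smallest total (-1.115 ± 0.715, edgeR adjusted p = 0.222). Fibroblast markers gave adjusted p = 0.00432 by camera and adjusted p = 0.0584 with an estimated correlation.

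DNA replication turned the other way: 34 of 38 members were lower at 10 nM than at 0.06 nM, 36 when adjusted over the list alone, with a median of -0.53. DNA replication genes gave adjusted p = 1.15e-10 by camera and adjusted p = 0.282 with an estimated correlation. MCM3 fell from 157 ± 5.78 to 88.6 ± 6.95 CPM (-0.82 ± 0.065), CDT1, a licensing factor, by 0.88 ± 0.082, and PCNA, the sliding clamp, by 0.63 ± 0.064. DNA repair genes were lower in 18 of 23, 19 when adjusted over the list alone, with XRCC5, XRCC4 and LIG4 higher; XRCC2, of homologous recombination, changed by -0.96 ± 0.09. DNA repair genes gave adjusted p = 0.00158 by camera and adjusted p = 0.439 with an estimated correlation. Ribosome biogenesis genes were lower in 13 of 28 with GNL3 and RRP12 higher, a list call lost without 0.06 nM replicate 2. Ribosome biogenesis genes gave adjusted p = 0.023 by camera and adjusted p = 0.556 with an estimated correlation. The mitosis list was not called (camera adjusted p = 0.42); BUB1B and AURKB, chosen after their values were seen, were lower, BUB1B alone when adjusted over the list, and 30 of 32 members did not pass the test. Glycolysis was not called by camera either, with 7 members higher and 5 lower (PFKP, PFKFB3, PFKM, PKM and GPI), although fry called it higher. Over all genes edgeR called 8341 between the doses, 4182 higher and 4159 lower at 10 nM, and 733 and 1065 changed at least 2-fold. Counts of members of the other called lists were the same when adjusted over the list alone. With library totals alone the median moved by -0.179 and the calls were 2333 higher and 7043 lower, with 37 DNA replication genes lower and 20 unfolded protein response genes higher.

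A response that turns with dose was counted as a gene called one way at 0.06 nM against vehicle and the other way at 10 nM against 0.06 nM. TERT, the catalytic subunit of telomerase (ENSG00000164362.21, chromosome 5, 1253147 to 1295069, minus strand), rose from 2.15 ± 0.416 to 6.59 ± 0.614 CPM at 0.06 nM and was back at 2.38 ± 0.458 CPM at 10 nM (log2 1.62 ± 0.17 and -1.49 ± 0.17). The other clearest peaks were ZPLD1 (1.37 ± 0.17 and -1.64 ± 0.17), THBS1, thrombospondin, which lies opposite FSIP1 (1.68 ± 0.13 and -1.25 ± 0.13), CDCA7 (1.07 ± 0.073 and -0.95 ± 0.073), E2F2, an E2F transcription factor (1.19 ± 0.11 and -0.94 ± 0.11), and TONSL, a factor of replication fork repair (0.99 ± 0.078 and -0.93 ± 0.078). MYC peaked as well, at 206 ± 7.89 CPM, and ended below vehicle. Troughs went the opposite way: SOX9, a lineage transcription factor, fell from 10.5 ± 2.52 to 4.66 ± 0.753 CPM and then rose to 19.9 ± 1.75 CPM (-1.19 ± 0.20 and 2.10 ± 0.20). CDKN2B, the cell cycle inhibitor p15, changed by -1.01 ± 0.15 and 2.40 ± 0.14, and GADD45G, a growth arrest gene, by -0.88 ± 0.081 and 2.54 ± 0.08, both ending above vehicle. WNT5A, a secreted ligand (-0.83 ± 0.14 and 1.40 ± 0.14), SLCO4A1-AS2 (-0.83 ± 0.13 and 0.92 ± 0.13) and NUCB2, the precursor of nesfatin (-0.91 ± 0.14 and 0.77 ± 0.14), were the other named troughs.

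In all, 1159 genes turned, 742 as peaks and 417 as troughs; with library totals alone there were 1080 peaks and 219 troughs. At 10 nM, 414 of the peaks were not called against vehicle, 230 remained above it and 98 lay below it. DNA replication genes made up 34 of the peaks out of 38 tested, against 1.53 expected (Fisher's exact test, two-sided, adjusted p = 5.63e-42 over 48 tests), DNA repair genes 17 of 23 (0.927 expected, adjusted p = 3.18e-18) and ribosome biogenesis genes 11 of 28 (1.13 expected, adjusted p = 7.8e-08). Genes of a list are not independent of each other, which Fisher's test assumes. Mitosis genes gave 2 peaks of 32 (adjusted p = 1), BUB1B and AURKB. The count became 8 with no low-count filter, 11 with the replicate number as a block and 7 without the 5 libraries numbered 3. Among troughs, cell cycle inhibitors (3 of 14: CDKN1B, CDKN1C and CDKN2B) and glucocorticoid-responsive genes (3 of 13: DUSP1, KLF9 and TSC22D3), chosen after their values were seen, each had adjusted p = 0.0335; with library totals alone each list had 1, without the 5 libraries numbered 3 each had 2, and cell cycle inhibitors also had 2 with RLE size factors, DESeq2 or thinning. A stricter count, genes called in opposite directions at 0.06 nM and 10 nM each against vehicle, gave 224, and 464 genes turned when the 0.03 nM call replaced the 0.06 nM call against vehicle, so that no library entered both calls.

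**Figure D4:**
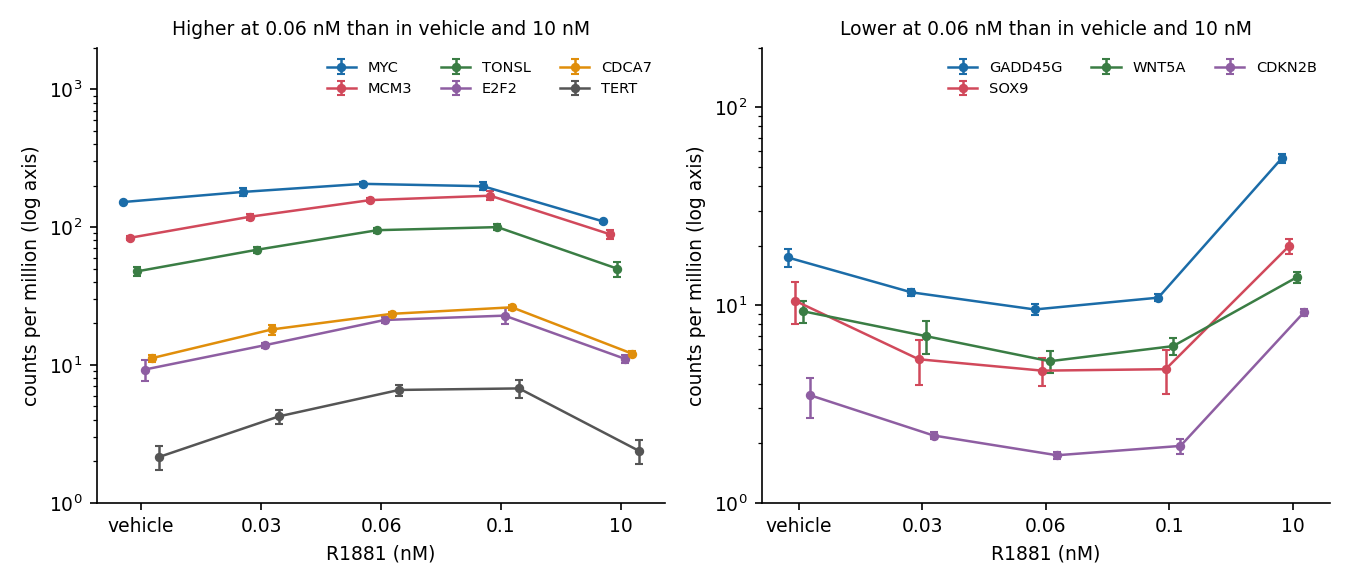
CPM on a log axis (mean ± SD, n = 3) by R1881 dose for 6 peaks (MYC, MCM3, TONSL, E2F2, CDCA7, TERT) and 4 troughs (GADD45G, SOX9, WNT5A, CDKN2B). TERT stood at 2.15 CPM in vehicle, 6.59 at 0.06 nM and 2.38 at 10 nM.

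Across the 18403 genes the low-dose and high-dose changes against vehicle largely had the same direction. Of the genes called at 0.06 nM, 2414 were higher and 2075 lower at both 0.06 and 10 nM, where 913.6 and 745.3 would be shared if the calls were independent, and 98 and 126 were called in opposite directions. The fold changes correlated across genes with r = 0.608 for 0.03 nM, 0.756 for 0.06 nM and 0.84 for 0.1 nM against 10 nM (Spearman 0.517, 0.672 and 0.758); genes are not independent replicates. The vehicle libraries enter both fold changes, and 20 simulated sets of unchanged groups gave r of 0.509, 0.498 and 0.504 on that ground alone. The covariance was 0.0233 in these sets and 0.233, 0.425 and 0.589 in the data. At most 1 gene was called in any comparison of these sets with vehicle. They therefore cannot show how many shared calls the common vehicle libraries add, and the counts under independence leave this out as well.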

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

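The alternatives chosen only after the results were seen are library totals alone, the thinning of all libraries to the smallest total, and the fits without the 5 libraries numbered 3. No named value, and no list that was called, turned into a call in the opposite direction under any alternative run, although lists without a call changed sign in some, as ATF4 targets did at 0.03 nM without vehicle replicate 3. Of 5495 named values over all alternatives 5374 stayed on the same side of the threshold, 91 lost their call and 30 gained one. At 0.03 nM against vehicle, 1588 genes became 3195 with the replicate number as a block and 1008 with only the compared libraries, and ran from 979 (without vehicle replicate 4) to 1309 with 1 library left out. The 1159 non-monotone genes became 1769 with the block, 464 with the 0.03 nM call in place of the 0.06 nM call and 224 with both doses against vehicle, and ran from 829 (without 0.06 nM replicate 2) to 1071; the last 2 definitions ask for other calls, and the cause of the other changes was not tested. With 1 library left out, calls ran from 4493 to 5140 at 0.06 nM, 6771 to 7195 at 0.1 nM, 9600 to 10063 at 10 nM and 7208 to 7694 for 10 nM against 0.06 nM, and lists called from 10 to 14, 13 to 14, 14 to 15, 16 to 16 and 13 to 14 over the 5 comparisons. Camera with an estimated correlation called 1 list at 0.03 nM, 1 at 0.06 nM (androgen-induced genes in both), 2 at 0.1 nM (with hexosamine and polyamine synthesis), 3 at 10 nM (with the unfolded protein response) and 3 for 10 nM against 0.06 nM (the last 2 and luminal markers). With the replicate number as a block as well, this test called no list in any comparison; the lowest adjusted p was 0.0828, the value of androgen-induced genes in all 5, and the unfolded protein response had 0.0931 at 10 nM. Under the block, camera with its preset correlation added the unfolded protein response at 0.03 nM (adjusted p = 0.0485) and the insulin-like growth factor axis at 0.06 and 0.1 nM (0.0328 at both), lost glucocorticoid-responsive genes at 0.1 nM (0.0917) and changed no other list call, and 11 mitosis genes were peaks in place of 2. The planned main fits did not use the replicate numbers as pairs. Across groups, 23 of 30 same-number pairs correlated above 0.1 (-0.014 to 0.315). Each of the 15 libraries lay closest to its own number (median correlation 0.152 against -0.087 for other numbers). Libraries of the same number thus shared differences that the main fits count as spread within groups. VCaP alternatives, the line interaction and the overlap between lines were not run. Depth limits genes with few counts, such as ERG, and 3 libraries per group limit small changes: simulated changes of a log2 of 0.5 were recovered in 50.7% of cases at 0.06 nM.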

Other observations

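The gene sets and genes given in the accounts of partial and high-dose-only responses were picked only after the results were seen, as were the tests on scaling, on fibroblast markers, on UGT2B genes and on dividing cells and the fits without the libraries numbered 3; the tests on GC content and other splits were set before their results, as was the bound for those fits. The test on scaling replaced an earlier one, with library totals alone (37 DNA replication genes lower at 10 nM than at 0.06 nM), because that setting lowers all genes and so could not speak against scaling. The androgen-induced genes differed in how much of their 10 nM change was reached at low dose. At 0.1 nM, KLK3 had reached 83.1% of its log2 change at 10 nM, against 56.5% for FKBP5, 32.8% for NDRG1 and 12.3% for TIPARP, the lowest of the 28 (median 67.35%). Of the 28, 26 were still higher at 10 nM than at 0.1 nM; KLK4 was not called between these doses (edgeR adjusted p = 0.1), and TRPM8 was lower at 10 nM (log2 -0.45 ± 0.16, adjusted p = 0.035).

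A further set of genes was called only at 10 nM: 1454 were higher and 971 lower at 10 nM than in every other group with no call at the 3 low doses, 195 and 295 of them by at least 2-fold against vehicle. Interferon response genes made up 8 of the lower ones out of 21 tested, against 1.11 expected (CMPK2, IFI44L, IFI6, IFIH1, IFIT1, IFIT2, IFIT3 and ISG15; Fisher's exact test, two-sided, adjusted p = 0.000308 over 48 tests); p53 targets, with 5 of 20 (BAX, DDB2, FAS, PLK3 and SPATA18), did not pass (adjusted p = 0.0517). Outside this set, since it was also called at 0.1 nM, KRT8, a luminal keratin, stood at 479 ± 14.3 CPM in vehicle, 466 ± 18.4 at 0.06 nM, 546 ± 12.3 at 0.1 nM and 2930 ± 252 CPM at 10 nM. Its partner KRT18, also called at 0.06 and 0.1 nM, went from 367 ± 2.8 to 1780 ± 86.5 CPM. KRT8 and KRT18 overlap on opposite strands of chromosome 12, and the strand setting of the counting is not given, so some reads may be shared. In the insulin-like growth factor axis the receptor IGF1R was above vehicle at each dose, with 20, 36, 71.2, 105 and 275 ± 10.6 CPM, and the adaptor IRS2 went from 3.58 ± 0.563 to 29.3 ± 2.63 CPM, although camera called the list as a whole only under some alternatives, such as library totals alone at 0.06, 0.1 and 10 nM. Among ETS factors SPDEF rose from 71.1 ± 3.43 to 419 ± 25.8 CPM and ELK4 from 142 ± 8.83 to 385 ± 40.8 CPM, while ELF3 fell from 24.6 ± 1.25 to 13.7 ± 0.435 CPM. ENO2, a neuronal enolase used as a neuroendocrine marker, fell from 52.6 ± 3.04 to 18.2 ± 1.2 CPM (SD, n = 3).

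DNA replication genes were higher at 0.06 nM than in vehicle and lower again at 10 nM. The tables argue against 3 technical causes, the first 2 only for the fall from 0.06 nM to 10 nM. After removal of a smooth trend on GC content and transcript length, the list's median change between these doses was -0.501 (from -0.532). Of its members 38 of 38 then lay below 0. A scaling factor moves every gene of a library alike. Yet the list's median change minus that of all tested genes was -0.506, with 38 of 38 members below the latter. Without the 5 libraries numbered 3, 36 members were both higher at 0.06 nM and lower at 10 nM. The rise at 0.06 nM over vehicle was not tested for the first 2 causes. A lower share of dividing cells at 10 nM would lower mitosis genes alike. The replication level minus the mitosis level was 0.375 ± 0.108 at 0.06 nM and -0.064 ± 0.131 at 10 nM (SD, n = 3). This difference of 0.439 lies within the summed ranges of 0.446 (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows). Those ranges include differences shared by libraries of the same number, which were not used as pairs. Between libraries of the same number, compared later, the difference was 0.415, 0.413 and 0.490 (SD 0.044). These values argue against an equal fall of both lists. A lower share of dividing cells as a part of the cause stays open. Of 32 mitosis members 2 were called lower, BUB1B and AURKB. More peaked without the libraries numbered 3 (7), with no low-count filter (8) and with the replicate block (11), which goes with a fall of some mitosis genes. In the same fits 36, 35 and 37 of 38 replication members peaked, a far larger share. The clause that asks for many mitosis members was added after the values were seen. Without it the explanation by dividing cells would have passed its test on the summed ranges. Fewer cells in S phase or lower transcription of these genes per cell may each account for the pattern, and neither was tested directly.

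The 6 fibroblast markers were lower at 10 nM. Fibroblasts mixed into the vehicle cultures would bring decorin (DCN) with type I collagen. The vehicle libraries, however, held 0.0235 DCN counts per 100 COL1A1 counts (1 DCN count against 4253). This is far under the bound of 1 per 100, which was chosen after the results were seen. Of the 12 listed markers 6 had enough counts in these cells to be tested, and LNCaP cells themselves may be the source of the transcripts; the dose itself, as the biological difference of the design, stays open and was not tested further.

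UGT2B15 and UGT2B17, enzymes that inactivate androgens by glucuronidation, fell from 155 ± 91.6 to 12.3 ± 7.14 and from 156 ± 68 to 19.8 ± 8.88 CPM at 10 nM, while their paralogs UGT2B11 and UGT2B28 rose from 8.9 ± 6.75 to 54.6 ± 32.8 and from 0.446 ± 0.196 to 23.7 ± 12 CPM (SD, n = 3). Reads of the first pair assigned to the second would make both pairs fall together, but the summed CPM of UGT2B11 and UGT2B28 rose by a log2 ratio of 3.068, with 0.753 as the smallest ratio of any 10 nM library over any vehicle library. The bound for this test was lowered from a ratio above 1 to a ratio above 0 after the values were seen; under the first bound the outcome would be undecided. Reads shared at a constant rate between UGT2B11 and UGT2B28 would keep their counts in 1 ratio, but the lowest ratio at 10 nM was 3.44 times the highest in vehicle (means 0.473 and 0.0699). Opposite regulation of these paralogs by the high dose may account for the pattern; how the counting treated reads that match several of them is not given.

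Other splits of the same libraries were counted for each comparison. For each of the 5 pairwise comparisons, fitted on its 6 libraries, only the real split of 10 (1 of 10) gave as many genes: 1008 at 0.03 nM, 5468 at 0.06 nM, 7271 at 0.1 nM, 10196 at 10 nM and 8136 for 10 nM against 0.06 nM, with 0 in the highest other split; 10 splits are too few for a share under 0.05. For non-monotone genes, 3 of 100 drawn assignments of the 9 libraries gave at least the real 1143. The other 2 gave 4423 and 1432 and both had all 3 vehicle libraries in the middle role, so they follow the structure of the samples. The remaining 97 gave 0. Assignments that mix doses carry the dose differences into the spread within groups, which leaves few or no calls. The share of 3 in 100 therefore speaks only against labels without any effect. It cannot tell whether single genes turned by chance.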
